A study of Homo sapiens with 8 samples.

How the data were processed

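Gene expression was measured in MOLM-14 cells, an established human acute myeloid leukaemia line, after 72 h of doxycycline, which per the labels switched on a short hairpin RNA. The hairpin was directed against ENTPD1, the gene of the ectonucleotidase CD39 (shCD39, 4 arrays), or was a control hairpin (shCTRL, 4 arrays). Per the labels' protocols, total RNA was turned into biotinylated cRNA with the GeneChip WT PLUS kit and hybridised to Affymetrix arrays. Array model and genome build are not given in the sources used here, so no coordinates are printed. The labels call all 8 arrays technical replicates, so p-values measure only the spread between these arrays. The labels partly spell the cell line MOML14; it was read as the same line.

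The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA in the oligo package, without a version; RMA corrects the background, sets all arrays to a shared distribution and summarises the probes of a probe set. That step removes any difference in total RNA between arrays, so a change is always relative to the bulk of probe sets. The table held 53617 probe sets on 8 arrays, with array medians between 3.13 and 3.17 on the log2 scale. Correlations between arrays ran from 0.980 to 0.992, and 0 pairs of arrays were identical. Arrays give no read depth; their number limits the precision.

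Gene names came from the platform annotation supplied with the values, updated through Entrez IDs against a RefSeq gene table of assembly GRCh38.p14, used for names only. A symbol was found for 16098 probe sets, all with exactly 1 symbol, and 37519 probe sets are unnamed here. Each gene was represented by its probe set with the highest mean over all arrays, which gave 14884 genes, of which 11916 were protein-coding and 779 had more than 1 probe set. No filter on dim genes was applied.

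The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on the deposited log2 values, with 2-sided tests and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05, and a second count required a change of at least 2-fold. Fold changes are shCD39 minus shCTRL on the log2 scale, with the standard error (SE) of the fit, and values per group are mean ± SD. Single values were also compared with a 2-sided exact permutation test, whose smallest p for 4 against 4 arrays is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

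Gene lists were written down before the data were examined: 36 lists covering purinergic signalling, cAMP, mitochondria, metabolism, stress responses, cell cycle, myeloid and leukaemia genes, and markers of other cell types. Of their 862 genes, 491 had a probe set named here, and these are called measured. Other members may lie among the 37519 unnamed probe sets, so a gene not measured here is not shown to lack probes on the array. Coverage differed between lists, with 48 of 49 genes of the mitochondrial ribosome and 0 of 37 of respiratory complex I. Lists with at least 2 measured genes (33 lists) were tested with limma's camera at a preset correlation of 0.01 between genes; camera with an estimated correlation and fry served as alternatives. The lists of respiratory complex I and of mitochondrially encoded genes had 0 measured genes and were not analysed here, and the MHC class II list had 1. Members were also adjusted over the list alone. A list score is the mean over its genes of an array's log2 deviation from the shCTRL mean.

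The genes named in the text follow a rule fixed beforehand. It takes ENTPD1; up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap, leaving out names of the style of pseudogenes, small RNAs, antisense or intergenic transcripts and numbered open reading frames; and, per list, up to 4 members past the threshold or otherwise up to 2 with the largest change, given as values. MFAP4 and C19orf38, and list members printed only with a value adjusted over the list alone, fall outside it and were chosen after their values were seen. TP53INP1 entered through its list.

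Alternatives fixed beforehand were quantile, median and cyclic loess normalization, a filter on dim genes, the mean of all probe sets of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array in turn, all probe sets, limma's treat with 1.2-fold, and a minimum change of 1.5-fold. Leaving out both arrays numbered 4 was added after seeing the data. The procedure was tested on simulated data of the shCD39 against shCTRL comparison with 14884 genes, 200 of them changed: 8.5% were recovered at a log2 change of 0.5, 87% at 1 and 100% at 2. With 1 list shifted, 1 of 33 lists was called, the shifted one. The simulated genes varied independently of each other, so false calls of lists of correlated genes were not tested.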

Results

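The data comprised 8 arrays of MOLM-14 leukaemia cells, 4 expressing a hairpin against ENTPD1 and 4 expressing a control hairpin, all after 72 h of doxycycline. The series set out to find genes whose expression depends on CD39, an enzyme of the cell surface that splits extracellular ATP and ADP. The single comparison of the design was therefore shCD39 against shCTRL.

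ENTPD1 itself was lower in the shCD39 arrays, but not past the threshold. Its single probe set read 2.56 ± 0.35 in shCD39 and 3.34 ± 0.54 in shCTRL (log2, mean ± SD, n = 4 arrays each), a log2 fold change of -0.79 (SE 0.25, limma adjusted p = 0.178). The shCD39 arrays 1 to 4 read 2.42, 2.14, 2.72 and 2.95, and the shCTRL arrays 3.16, 2.88, 3.21 and 4.12. The groups overlapped by shCD39 array 4 and shCTRL array 2, and the exact permutation p was 0.0571. Without shCTRL array 4 the log2 fold change was -0.53.

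Of 14884 genes, 14 passed the threshold, 7 higher and 7 lower in shCD39, and 7 of these changed at least 2-fold (3 higher, 4 lower). The genes that rose included p53 targets. TP53INP1, a p53-induced regulator of cell death and autophagy, rose from 4.31 ± 0.22 to 5.79 ± 0.24 (2.78-fold, SE 0.15 on the log2 scale, adjusted p = 0.00716). PURPL, a long non-coding RNA induced by p53, rose 3.10-fold, from 4.86 ± 0.33 to 6.49 ± 0.40 (adjusted p = 0.0193). SESN1, a stress-induced inhibitor of mTORC1 signalling, rose 2.48-fold, from 6.84 ± 0.33 to 8.16 ± 0.37 (adjusted p = 0.0432). RRM2B, the p53-inducible subunit of ribonucleotide reductase, rose 1.92-fold (log2 0.94, SE 0.11, adjusted p = 0.00993).

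The other genes that rose were DOCK9, an activator of the GTPase CDC42 (log2 0.96, SE 0.11), MSMO1, an enzyme of cholesterol synthesis (0.88, SE 0.12), and TFEC, a transcription factor of the MITF family (0.85, SE 0.13). The largest fall was that of STC2, a secreted glycoprotein, from 6.97 ± 0.46 to 5.18 ± 0.59, or 3.46-fold lower (adjusted p = 0.048). SKA1, a protein of the spindle and kinetochore, fell 2.17-fold (log2 -1.12, SE 0.18), and the zinc finger gene ZFP69B fell 2.02-fold (log2 -1.02, SE 0.15). AKNA and the stress-induced transcription factor ATF3 fell with log2 fold changes of -0.91 (SE 0.14) and -0.75 (SE 0.11). MFAP4, a protein of the extracellular matrix, fell 3.23-fold and C19orf38 1.95-fold; both were chosen after their values were seen. In all 14 genes the 4 shCD39 values lay entirely on one side of the 4 shCTRL values.

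The count depended on single arrays. Without shCD39 array 4 it was 423 genes (111 higher, 312 lower, all 14 among them), without shCTRL array 4 it was 48, and without shCTRL array 1 limma called 0, with 1574 at an unadjusted p under 0.05. Quantile normalization left 5 genes, all higher, and cyclic loess 10, of which 70% were higher against 50% as deposited. At an unadjusted p under 0.05 there were 2183 genes, 973 higher and 1210 lower. The groups did not overlap in 1168 genes, or 7.85%. Chance gives 2.86% on average, but the share was not computed for other splits of the arrays, so an excess was not tested.

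**Figure D1:**
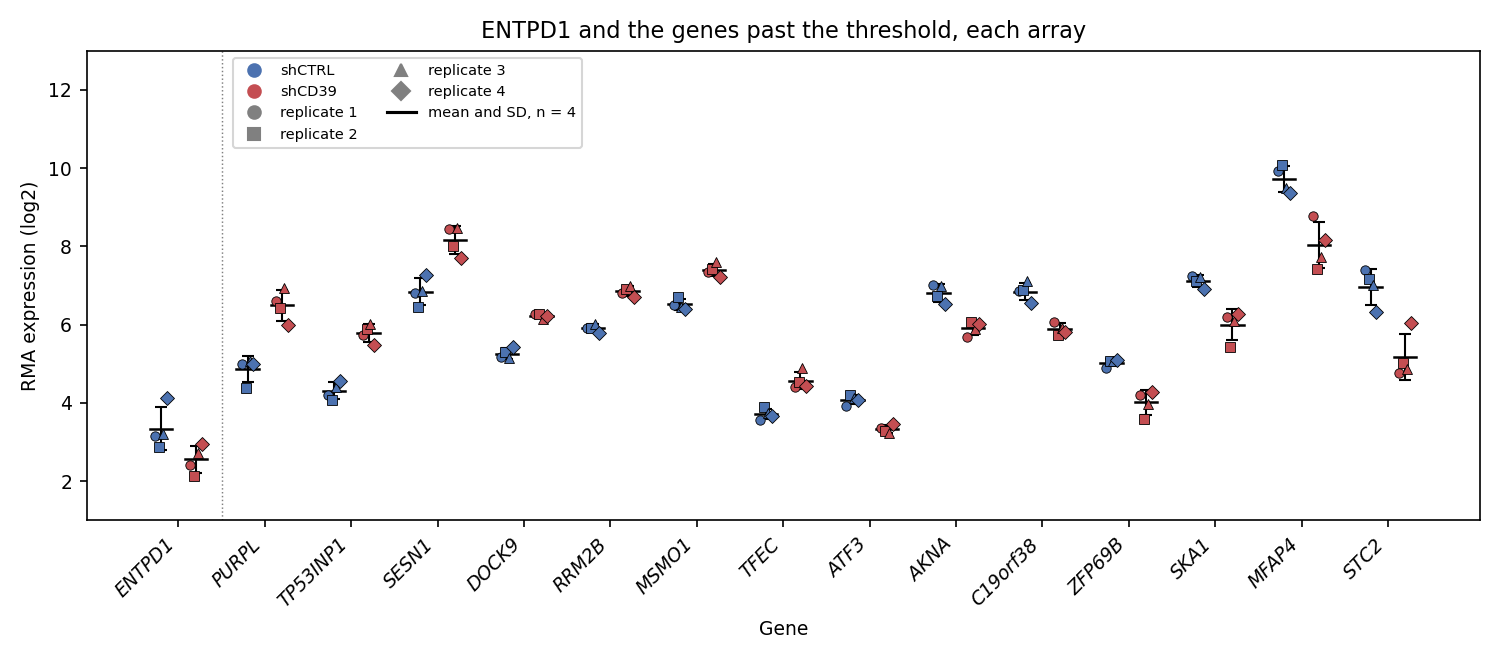
Expression of ENTPD1 and of the 14 genes past the threshold, as RMA values on the log2 scale, for each of the 8 arrays (blue shCTRL, red shCD39, symbols give the replicate number), with the mean and SD of each group. For each of the 14 genes the groups do not overlap, while for ENTPD1 they do.

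Among the 33 gene lists tested, 12 passed camera with the preset correlation, 5 higher and 7 lower in shCD39. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.267, and by fry 0 passed. At an unadjusted p under 0.05 these tests gave 4 and 14 lists.

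Genes of DNA replication were lower throughout. All 23 measured members of the E2F and DNA replication list had lower means in shCD39, with a median log2 fold change of -0.55 (camera adjusted p = 2.13e-16, adjusted p = 0.267 with an estimated correlation). None passed over all genes, or 13 without shCD39 array 4, and 21 were lower when adjusted over the list alone. CDT1, which licenses replication origins, had a log2 fold change of -0.99 (SE 0.21, adjusted p = 0.0849), and the helicase subunit MCM2 one of -0.91 (SE 0.22, adjusted p = 0.109). The 23 genes of G2 and mitosis were likewise all lower, with a median of -0.41 (adjusted p = 2.62e-10, adjusted p = 0.298 with an estimated correlation). None passed over all genes, or 7 without shCD39 array 4, and over the list alone 1 did, the mitotic kinase PLK1 (-0.92, SE 0.23); HMMR stood at -0.76 (SE 0.29), or -0.46 without shCD39 array 3, and in shCD39 array 4 it read above every shCTRL array. The scores of shCD39 array 4 on both lists lay inside the shCTRL range (exact permutation p = 0.0571 for E2F and 0.0857 for G2 and mitosis).

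Amino acid synthesis and stress genes driven by ATF4 had the largest median shift of the 33 lists. Of 19 measured members, 18 were lower, with a median of -0.91 (adjusted p = 1.53e-15, adjusted p = 0.267 with an estimated correlation); 0 passed over all genes, 10 without shCD39 array 4 and 6 without shCTRL array 4, and 16 were lower when adjusted over the list alone. CTH, an enzyme of cysteine synthesis, read 4.98 ± 1.13 in shCD39 and 7.09 ± 0.58 in shCTRL (log2 fold change -2.10, SE 0.46, adjusted p = 0.0908). TRIB3, a pseudokinase induced by ATF4, had -1.88 (SE 0.38, adjusted p = 0.0805). The groups overlapped on this list: shCTRL array 4 scored -0.58, below shCD39 array 4 at -0.50, and the exact permutation p of the scores was 0.0571.

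The p53 target list was higher, with 7 of 11 measured genes positive and 4 negative and a median of 0.26 (adjusted p = 0.000198, adjusted p = 0.267 with an estimated correlation). TP53INP1, SESN1 and RRM2B rose over all genes, though 0 did without shCTRL array 1, and 5 members did when adjusted over the list alone, with BAX and TIGAR as the others. Markers of monocytes and macrophages were higher in 19 of 21 measured genes, with a median of 0.15 (adjusted p = 3.23e-05, adjusted p = 0.312 with an estimated correlation). None passed over all genes, or 5 without shCD39 array 4 and 1 without shCTRL array 4, and 6 were higher when adjusted over the list alone. The monocyte score of shCD39 array 4 lay inside the shCTRL range (exact permutation p = 0.0571). The receptor CSF1R had a log2 fold change of 1.36 (SE 0.29, adjusted p = 0.0849), and FGL2, a secreted immune regulator, one of 1.18 (SE 0.40, adjusted p = 0.199). Fibroblast and epithelial markers were higher as well, in 7 of 7 genes with a median of 0.21, though short of the threshold (adjusted p = 0.055).

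All 16 measured genes of MYC and ribosome biogenesis were lower, with a median of -0.20 (adjusted p = 8.74e-06, adjusted p = 0.267 with an estimated correlation), 4 of them when adjusted over the list alone; MYC itself had -0.61 (SE 0.16) and NOP58 -0.47 (SE 0.12). Of 48 genes of the mitochondrial ribosome, 35 were lower, with a median of -0.09 (adjusted p = 0.00364, adjusted p = 0.312 with an estimated correlation) and 0 past the threshold over the list alone; MRPS35 had -0.47 and MRPS27 -0.42. Of 17 genes of mitochondrial biogenesis, import and dynamics, 14 were lower (median -0.16, adjusted p = 0.00697, adjusted p = 0.267 with an estimated correlation). HSPA9, the mitochondrial HSP70, had -0.52 and passed over the list alone, and OPA1, which fuses inner membranes, had -0.55 (SE 0.27), or -0.30 without shCD39 array 3; in shCD39 array 4 it read above every shCTRL array, and the score of that array on the list lay inside the shCTRL range (exact permutation p = 0.0571). Targets of KMT2A fusions, oncoproteins of a class of acute leukaemias, were lower in 11 of 12 genes (median -0.22, adjusted p = 0.00569, adjusted p = 0.349 with an estimated correlation). BCL2, an inhibitor of apoptosis in that list, had -0.80 and passed over the list alone; SENP6 had -0.53 (SE 0.28), or -0.32 without shCD39 array 1. The scores of this list were -0.43 and -0.50 in shCD39 arrays 1 and 3, while those of arrays 2 and 4, -0.09 and 0.01, lay inside the shCTRL range (exact permutation p = 0.143).

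The purinergic list, which holds the other enzymes and receptors of extracellular nucleotides, was higher in 11 of 15 genes (median 0.09, adjusted p = 0.0447, adjusted p = 0.267 with an estimated correlation). CD38, an ectoenzyme that consumes NAD, had 0.80 (SE 0.16, adjusted p = 0.0801) and adenosine deaminase (ADA) 0.50 (SE 0.13, adjusted p = 0.131); both passed over the list alone. The NRF2 list was higher in 9 of 12 genes (median 0.08, adjusted p = 0.0447, adjusted p = 0.267 with an estimated correlation), with catalase (CAT) at 0.78 past the threshold over the list alone and PRDX1 at 0.35. The NF-kB list was higher in 10 of 16 (median 0.14, adjusted p = 0.0429, adjusted p = 0.267 with an estimated correlation), with the chemokine CCL4 at 0.78 past the threshold over the list alone and TNF at 0.46. Without shCD39 array 4 the purinergic list (adjusted p = 0.0648) and the NRF2 list (adjusted p = 0.0987) no longer passed, and the adhesion list did (adjusted p = 0.0474). Over all genes and without that array, 2 purinergic genes, 1 NRF2 gene and 1 NF-kB gene rose, and 2 genes of the mitochondrial ribosome and 1 each of the mitochondrial biogenesis, MYC and KMT2A lists fell, against 0 with all arrays. The NRF2 and MYC lists each had 1 such gene without shCTRL array 4 as well, and the NF-kB list 1 without shCD39 array 2.

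The remaining lists did not pass. Over all genes and without shCD39 array 4, 2 heat shock genes, 2 apoptosis genes, 1 cAMP gene and 1 adhesion gene rose, against 0 with all arrays. In that setting 1 hypoxia gene and 1 apoptosis gene fell, and without shCTRL array 4, 1 hypoxia gene and 1 interferon gene did. Genes of respiratory complexes II to V had a median of 0.02 over 16 genes (camera adjusted p = 0.796), with COX5B at 0.25 and COX7A2L at -0.23. The tricarboxylic acid cycle had -0.04 over 11 genes (0.17; CS -0.42, DLAT -0.34), fatty acid oxidation 0.08 over 9 (0.794; CD36 0.63, CPT1A 0.50) and hypoxia targets -0.02 over 13 (0.796; VEGFA -1.33, DDIT4 -0.79). Over the list alone CD36 and CPT1A were higher and ECI1 and HADH lower, and VEGFA was lower. In glycolysis the median of 0.03 and the mean of -0.06 differed in sign (adjusted p = 0.722; LDHB -0.62, or -0.34 without shCD39 array 3, and HK2 -0.33). Genes of cholesterol and fatty acid synthesis had a median of 0.10 over 21 (adjusted p = 0.276), with MSMO1 the member that rose over all genes, and 2 higher and 2 lower over the list alone.

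Targets of cAMP and CREB had a median of 0.03 over 9 genes (adjusted p = 0.99), where the test pointed lower; ATF3 fell over all genes and over the list alone, where FOS was higher. Adenylyl cyclase and PKA components had 0.04 over 17 (0.93; CREB1 -0.32, ADCY3 0.25). The unfolded protein response had a median of 0.12 over 9, with a mean just below 0 (adjusted p = 0.747; SEL1L -0.58, CRELD2 0.24). In the interferon list, 21 genes had a median of -0.03 although the test pointed higher (adjusted p = 0.99; XAF1 -0.48, IFI44 0.44). Heat shock genes had 0.13 over 7 (0.276), with HSPA1B at 0.72 and HSPA1A at 0.65 past the threshold over the list alone. In both genes the groups overlapped (exact permutation p = 0.0857 and 0.0571). There shCD39 array 4 read 7.50 and 7.34, below shCTRL array 4 at 7.66 and 7.50. Cytosolic ribosomal proteins had 0.01 over 22 (0.3; RPS19 0.31, RPS18 0.26).

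Granule genes of granulocytes had a median of 0.03 over 12 (camera adjusted p = 0.634); PRTN3 had 0.51, or 0.25 without shCTRL array 3, and MPO -0.40, or -0.14 without shCD39 array 3 and -0.15 without shCTRL array 4. The list of stem cell markers had 0.07 over 24 (0.17; SMIM24 0.45, NYNRIN 0.36). Regulators of apoptosis had 0.04 over 18 (0.235), with CFLAR at 0.64 and BCL2 at -0.80; over the list alone 3 were higher and 1 lower. In the cytarabine list, with a median of -0.33 over 9 genes (0.3), RRM2B rose over all genes and 5 members, RRM2 and DCK among them, were lower over the list alone. Without shCD39 array 4, 3 of its genes fell over all genes, and without shCTRL array 1 RRM2B did not pass. Adhesion and chemokine receptors had 0.16 over 10 (0.0548; PECAM1 0.77, SELPLG 0.41). CTSS, the measured gene of the MHC class II list, had 0.07.

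Markers of other cell types gave medians of 0.14 for T and NK cells over 11 genes (adjusted p = 0.0748; NKG7 0.50, PRF1 0.34), -0.06 for B and plasma cells over 6 (0.588; PAX5 -0.27, MZB1 0.19), 0.08 for erythroid cells and megakaryocytes over 6 (0.588; AHSP 0.26, KLF1 0.17) and 0.21 for fibroblasts and epithelium, 7 of 7 higher (0.055; THY1 0.29, KRT8 0.25). Of these, NKG7 passed over its list alone.

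**Figure D2:**
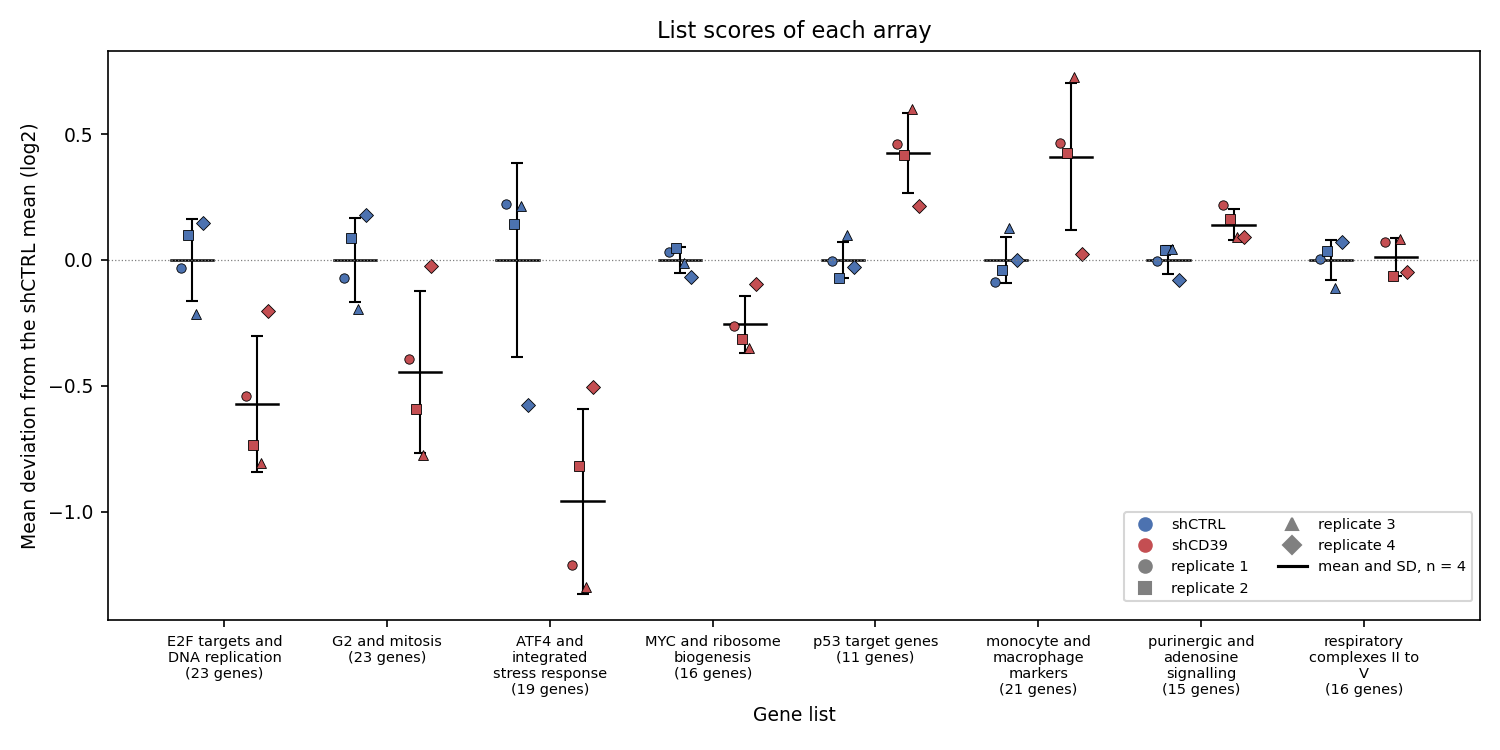
Scores of 8 gene lists on each of the 8 arrays, as the mean log2 deviation of the list's genes from the shCTRL mean (blue shCTRL, red shCD39), with the mean and SD of each group. The E2F score of shCD39 array 4, -0.20, lies inside the shCTRL range, which starts at -0.21, while its p53 score of 0.22 lies above the highest shCTRL score of 0.10.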

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

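The tests of a wrong or exchanged label on shCD39 array 4, the test of its correlations and the background test of ENTPD1, were chosen after the result was seen; the other tests were chosen beforehand.

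The shCD39 array 4 lay nearer to the shCTRL arrays than the other shCD39 arrays did. On an axis from the shCTRL mean (0) to the shCD39 mean (1) of the other arrays it scored 0.27. The other shCD39 arrays scored 1.2 to 2.02 and the shCTRL arrays -0.46 to 0.40. Each array had its own axis: the shCD39 mean held shCD39 array 4 for every array except that array itself. The scores are thus not on 1 scale, and the place of 0.27 inside the shCTRL range decides nothing alone. Of the 12 lists past the threshold, the scores of shCD39 array 4 lay inside the shCTRL range in 6. In 2 they lay beyond it by more than the shCTRL SD. Genes were then called without shCD39 array 4 and without 1 shCTRL array in turn. It lay beyond the other shCTRL arrays by more than the fitted SD in 39.8% to 57.3% of them. The held-out shCTRL array did so in 2.22% to 40.8%, and less often in each of the 4 fits. RRM2B read 6.70 in shCD39 array 4 against at most 6.01, and TP53INP1 5.48 against at most 4.56. Both are among the 14 genes called with this array in the fit, so they are not held-out evidence. Whether the array holds shCTRL RNA stays open. An exchange with a shCTRL array was not decided either: the highest shCTRL score was 0.40, that of shCTRL array 4, and the 4 exchanges gave at most 0 genes by limma but up to 11 lists, against 14 genes and 12 lists as labelled. Among the 100 genes with the lowest p without the array in question, shCTRL array 4 lay nearer to shCD39 in 58% and shCD39 array 4 in 20%. The mean correlation of shCD39 array 4 was 0.985 with its own group and 0.989 with shCTRL. That of shCTRL array 4 was 0.990 with its own group and 0.986 with shCD39. The shCD39 group split into pairs. Arrays 1 and 3 correlated at 0.98905 and arrays 2 and 4 at 0.98904, while the other pairs ran from 0.98154 to 0.98505. The value for shCD39 arrays 2 and 4 exceeded those of shCD39 array 4 with shCTRL arrays 1 to 3 (0.98854 to 0.98867). It was below that with shCTRL array 4, 0.99097. The cause of this split was not tested. For shCD39 array 4 the noise question was taken separately. Added noise in shCD39 array 4 as the whole cause is argued against, since its lowest correlation with a shCTRL array, 0.989, exceeded the highest of the other shCD39 arrays, 0.986, by more than their SD of 0.00193, while its interquartile range of deviations of 0.224 (highest 0.295) is small by construction for an array near the other group. A weaker knockdown was not tested.

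Lower cell cycle and ATF4 genes with higher p53 and monocyte genes were the pattern examined here. It is a choice among the lists past the threshold and not their ranking. The MYC list had a lower camera adjusted p (8.74e-06) than the monocyte (3.23e-05) and p53 (0.000198) lists. An intensity trend left by the normalization is argued against for the lists of this pattern, though only weakly for the monocyte list, just outside its range. Each median lay outside the central 95% of random lists of matched level: E2F -0.55 (lower bound -0.20), G2 and mitosis -0.41 (-0.18), ATF4 -0.91 (-0.18), p53 0.26 (upper bound 0.11) and monocyte 0.15 (0.10). The NF-kB median of 0.14 (0.11) did too. So did some lists that did not pass: fibroblast and epithelial markers 0.21 (0.18), adhesion 0.16 (0.15) and heat shock 0.13 (0.11). The unfolded protein response, 0.12 (0.10), cholesterol and fatty acid synthesis, 0.10 (0.06), and cytarabine, -0.33 (lower bound -0.26), lay outside as well. The genes of random lists were drawn independently, so a range is too narrow for a list of genes that vary together. Inside their ranges lay MYC -0.20 (lower bound -0.22), mitochondrial ribosome -0.09 (-0.15), mitochondrial biogenesis -0.16 (-0.22) and KMT2A -0.22 (-0.23). The same held for purinergic 0.092 (upper bound 0.119) and NRF2 0.085 (0.090), so a trend stays open for the lists inside their ranges. A growth state of the cultures apart from the hairpin cannot be told apart from an effect of the hairpin, because the labels name technical replicates and no independent cultures. The E2F scores of the groups had an exact permutation p of 0.0571, and within groups they correlated with the ATF4 scores at r = 0.18 and rho = 0.12 (exact permutation p = 0.698 and 0.806), or r = -0.67 without the 2 arrays farthest from the median. An effect of CD39 loss stays open and untested apart from these.

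ENTPD1 did not pass the threshold. Whether its probe set lies near the background was not decided: its shCTRL mean of 3.34 lay between the 5th and 95th percentile (1.53 and 7.13) of markers of other cell types, but so did 83.1% of all genes. No biological explanation was tested.

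Other splits of the 8 arrays into 4 and 4 test the counts against a chance labelling of these arrays. For 14 genes, 1 of 35 splits, the labelled one, gave as many, the highest other giving 1. For the 7 genes changed at least 2-fold it was again 1 of 35, the highest other giving 1, and for the 12 lists 1 of 35, the highest other giving 11. For both gene counts this share is under 0.05 and the smallest that 35 splits can give. The arrays are technical replicates, so the splits cannot exclude a chance difference between cultures or RNA samples. The list count exceeded the highest other split by 1 list and fell to 0 with an estimated correlation, so little rests on it.

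Single arrays stood apart from the other 3 of their group in 7 of 208 groups of values, where chance gives about 10.4. In shCTRL array 4, DDIT4 read 9.13, CTH 6.23 and XAF1 8.28, each below the others, and the ATF4 list scored -0.58 against 0.14 to 0.22. In shCTRL array 2, PURPL read 4.37, below the others. In shCTRL array 3, FGL2 read 6.85 and the unfolded protein response list scored 0.0834, both above the others.

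Among probe sets unnamed here, 4 passed the threshold when all probe sets were tested, all lower in shCD39. Their log2 fold changes were -3.92 (17095327), -1.53 (16654943), -1.46 (16655483) and -1.43 (16654661).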

How the results depend on the processing

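ENTPD1 stayed lower and short of the threshold under each alternative that kept it (the filter on dim genes removed it), from -0.94 to -0.53 with single arrays left out. The 14 genes became 5 with quantile normalization, 64 among genes above the median level, 22 with an intensity trend and robust prior, 124 with array weights and 1 with a minimum of 1.2-fold; leaving out single arrays gave 0 to 423 (0 without shCTRL replicate 1, where 1574 genes had an unadjusted p under 0.05), and leaving out both arrays numbered 4, chosen after seeing the data, 368. With all probe sets tested, 6 probe sets passed, 2 of them with a gene name. The 7 genes changed at least 2-fold became 4 with quantile normalization, 31 with array weights, 14 with a minimum of 1.5-fold, 0 to 79 with single arrays left out and 102 without both arrays numbered 4. The 12 lists became 0 with an estimated correlation and 0 by fry. The 5 higher and 7 lower lists became 2 and 7 with array weights and also without both arrays numbered 4. They became 3 and 7 with the replicate block and without shCTRL array 4, and 5 and 4 among genes above the median level. Without shCTRL array 3 they became 7 and 8. The cause of these shifts was not tested. Replicate numbers share only a number: deviations of arrays with the same number correlated at -0.01, -0.04, 0.05 and 0.06. With the replicate block 6 genes passed (4 shared) and 4 changed at least 2-fold, and all 6 were higher. Calls were all higher too without shCD39 array 3 (4 genes), shCTRL array 2 (5 genes) or shCTRL array 3 (3 genes). Of the named genes, 13 moved by over 1.5 times without a single array, 0 of them past the threshold; besides HMMR, OPA1, LDHB, SENP6, PRTN3, MPO and CTSS, the ranges were 0.16 to 0.30 for ADCY3, -0.30 to -0.15 for COX7A2L, 0.26 to 0.51 for PRF1, 0.08 to 0.29 for MZB1, 0.13 to 0.34 for AHSP and 0.10 to 0.23 for KLF1.

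Signs turned only in lists and a gene (CTSS) that did not pass, all near 0. The mean of the cAMP list became -0.000298 with arrays centred, -0.035 with the mean of probe sets and -0.00394 without both arrays numbered 4. Complexes II to V became -0.00574 with arrays centred. Among genes above the median level the mean became -0.032 for adenylyl cyclase, -0.028 for fatty acid oxidation, -0.044 for stem cell markers and -0.080 for erythroid markers. The unfolded protein response became 0.046 with quantile normalization and 0.049 with cyclic loess, and the interferon list 0.016 with quantile normalization. With single arrays left out the ranges were -0.060 to 0.191 for CTSS, -0.050 to 0.062 for the cAMP list, -0.00659 to 0.035 for adenylyl cyclase, -0.027 to 0.035 for complexes II to V, -0.018 to 0.024 for the unfolded protein response and -0.062 to 0.036 for the interferon list.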

Other observations

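Predictions for 3 further lists were written before their values were seen. They extended shifts already seen in the first lists and were tested on the same arrays. Genes that vary together on these arrays would shift in both the first and the further lists. A met prediction is therefore not independent evidence for a shift. Genes known as p53 targets beyond the first list had a median log2 fold change of 0.21 over 25 measured genes, above the central 95% of matched random lists (-0.09 to 0.09), and the scores of the arrays differed (exact permutation p = 0.0286, the smallest possible). Over all genes 0 members of any of the 3 lists passed. Adjusted over the p53 list alone, 10 were higher and 1 lower. Genes known as ATF4 targets beyond the first list had a median of -0.50 over 20 genes (random range -0.17 to 0.06, exact permutation p = 0.0286), 16 of them lower and 2, SESN3 and RIT1, higher over the list alone. The groups nearly met on this list, with shCD39 array 4 at -0.219 and shCTRL array 4 at -0.202. On the first ATF4 list these arrays stood in the opposite order. The further p53 and ATF4 lists both met their prediction, that the shifts extend to further targets, but neither passed camera with an estimated correlation (adjusted p = 0.0541 with an estimated correlation for each). By fry, which tests whether a list moves one way and not against other genes, both passed (adjusted p = 0.00903 each), as did the monocyte maturation list (adjusted p = 0.0289). The genes of monocyte maturation had a median of 0.30 over 16 genes (random range -0.15 to 0.09), 6 higher over the list alone, but an exact permutation p of 0.0571, so that hypothesis was left undecided (adjusted p = 0.0697 with an estimated correlation).

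Within groups, p53 scores followed the monocyte scores (r = 0.96, rho = 0.86) and ran against the E2F scores (r = -0.90, rho = -0.88) over the 8 arrays. Of 6 relations computed by exact permutation within groups, these had adjusted p = 0.0417 each for r and 0.0625 for rho; without the 2 arrays farthest from the median, r was 0.79 and -0.69. The arrays are technical replicates, so this is a description of these arrays.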
